A study of Arabidopsis thaliana with 6 samples.

How the data were processed

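Small RNAs were measured in mixed-stage inflorescences of Arabidopsis thaliana with 1 TruSeq small RNA library for each of 6 lines. The deposited tables give counts, the raw number of reads for each distinct sequence of 18 to 34 nt, with no normalization and no filter against the genome. Adapters had been removed and identical reads collapsed. The build was TAIR10, per the submitters' processing notes. The aligner, the adapter trimmer and the quality filter were not given in the sources used here.

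Sequences of 18 to 28 nt were placed on the TAIR10 chromosomes by exact match, with each read divided over its places, using python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. Between 16.5 and 19.7% of these reads had no exact match. Levels are reads-per-million (RPM) values, scaled to the 18-to-28-nt reads with an exact nuclear match outside rRNA, tRNA, snRNA and snoRNA and outside the organelle genomes. The annotation lacked the 25S rRNA, so 4000 nt past each 5.8S rRNA gene were counted as rRNA. Levels were also computed per read of 18 to 28 nt, per read of the listed miRNAs and, for miRNAs, with median-ratio size factors.

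For the Pol IV comparison, bins of 500 bp with at least 5 RPM of 24-nt reads in TS_delta35S were tested for a 4-fold fall, and bins within 3 Mb of an approximate textbook centromere position (15, 3.6, 14, 4 and 12 Mb on chromosomes 1 to 5) were counted apart. A miRNA read shared the first 18 nt of the mature sequence, was at most 24 nt long and matched the genome exactly. Mature sequences were written from general knowledge and used only where TAIR10 holds them. miRNAs with at least 20 reads over a pair were tested at 2-fold. Annotated loci outside structural RNA with at least 100 reads of 20 to 24 nt over a pair were tested at 4-fold, and members of the locus lists at 2-fold. For ranking and for list members, 0.5 RPM was added to both sides.

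Introduced sequence was read without a reference, since the sequences of the loci were not in the sources used here. Silencer-linked sequences of 20 to 25 nt had no genome match at up to 1 mismatch (searched from 5 reads), at least 10 reads in S_WT or S_delta35S and 10 times the level of T_WT there. Target-linked sequences met the same limits in T_WT against S_WT and S_delta35S. T_WT is therefore the reference for the target-linked set and no free readout. In lines with both loci, silencer-linked reads of the shared enhancer can also come from the target. Sequences were joined by overlaps of 16 nt into contigs of at least 50 nt. Probes of standard vector parts were 348 nt of the 35S promoter, 253 nt of the nos terminator, 720 nt of EGFP, and 351 and 465 nt of the starts of HPT and NPTII. Probe sequences were written from general knowledge and could not be checked against the introduced loci. Which of these the loci carry was not known beyond the 35S promoter and GFP, and a probe without reads says nothing about a locus.

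Folds are ratios of RPM with exact conditional Poisson intervals at 95%, and shares have exact Clopper-Pearson intervals. With 1 library per line no test between groups was run and no spread between plants is known. A fold against 0 reads was computed with a floor of 3 reads and is given as "at least", which is a bound at that floor and not a limit of the 95% interval. Fractional reads, which arise from division over places, were rounded to whole reads for folds and intervals, so folds of loci with few reads can differ from the ratio of their RPM. Several of the 5 pairs compared share a library, whereas the TS pair and the S pair share none. The TS pair and the S pair are still related by descent, since S_delta35S is a segregant of TS_delta35S.

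Loci were named by a rule: members of the lists that reached the read minimum, the 5 largest rises and falls of each pair, the 5 loci with the largest smaller change in the same direction in both 35S deletion pairs, and the 5 contigs with the most reads. The lists held 47 small RNAs (phase change, development, nutrient, silencing feedback, ta-siRNA triggers, pollen as a marker of another tissue, and others) and 22 loci (TAS, tandem-repeat RdDM, RdDM-regulated and silencing machinery). List medians were set against 10000 random lists of loci with like levels. The random lists were not matched for read length, so a percentile can reflect the read lengths of the members of a list. The groups, comparisons, lists, naming rule and main thresholds were fixed before the data were examined.

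Choices made after seeing the data were the 25S window, the bla probe of 861 nt, the wider choice of contigs (sequences seen in 2 of the 4 libraries with the silencer and functional Pol IV, contigs of at least 100 nt), and the split of contigs at 4-fold in the TS pair. They also include the set of sequences frequent in TS_WT and nearly absent with 1 locus alone, the bins present in some libraries and absent in others, the values of single loci per listed miRNA read, the ratios of miRNA folds between pairs under other scalings, and the tests of explanations. Because the TS pair defines the contig classes, their fold in that pair is not a free readout, and TS_delta35S_nrpd1 against TS_delta35S shares a library with it. The S pair did not define the classes, although its libraries were used to choose the sequences.

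The steps were tested on simulated data. Of 100 bins and 100 loci picked for each fold, falls of 8-fold were called in 100% and falls of 2-fold in 0%. The bins were picked at 2 times the minimum of 5 RPM or more, and the loci at 100 reads or more in TS_WT alone. Falls of features nearer to the minimum were therefore not tried. Of the unchanged features, 0 of 14722 bins and 0 of 6037 loci were called lower. The simulated counts held Poisson error only, without variation between plants or preparations. They therefore check the steps and do not show how often unchanged features are called in real libraries. Intervals held the true ratio in 96.8% of 500 draws. All 10 simulated sequences were recovered as contigs, and 1000 of 1000 words had the same number of places as in a text search. The simulated sequences were random and cut without errors, whereas the silencer holds an inverted repeat. The alternatives tried were the other scalings, minimums of 20 RPM for bins, of 30 reads for loci and of 5 or 50 reads for introduced sequences, reads with 1 place only, exact miRNA sequences only, exact genome matches only in the filter, and the silencer-linked choice from S_WT or S_delta35S alone. For bins, a fall of 2-fold and equal depth of both libraries were tried too, with 14582 and 14425 bins lost.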

Results

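Small RNAs of 18 to 34 nt were sequenced from mixed-stage inflorescences of 6 Arabidopsis thaliana lines, with 1 library per line and therefore no replicates. The lines combined a target locus, T, which carries a GFP reporter, with a silencer locus, S, in which a 35S promoter drives an inverted repeat of the target enhancer. T_WT held the target alone, S_WT the silencer alone and TS_WT both. TS_delta35S descended from TS_WT and had lost the 35S promoter of the silencer, and S_delta35S was its segregant without the target. TS_delta35S_nrpd1 carried in addition a mutation of NRPD1, the largest subunit of RNA polymerase IV (Pol IV), which makes the precursors of 24-nt siRNAs in RNA-directed DNA methylation (RdDM).

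The libraries held 33121771 reads in TS_delta35S, 27413670 in TS_delta35S_nrpd1, 32089383 in T_WT, 34526694 in S_WT, 35240561 in S_delta35S and 34410411 in TS_WT. Levels are reads-per-million (RPM) values, scaled to the reads of 18 to 28 nt with an exact nuclear match outside structural RNA, of which there were 10422189 to 20840439 per library. A floor of 3 reads corresponded to 0.144 RPM in TS_WT and 0.288 RPM in TS_delta35S_nrpd1. Bracketed ranges are exact 95% intervals, and they cover counting error only. PCR reads without molecular identifiers are not independent molecules, so these intervals can be too narrow even for counting error. The share of rRNA reads was 14.2% in TS_WT and 17.3% in T_WT, against 29.5% in S_delta35S, 34.5% in S_WT, 35.8% in TS_delta35S and 38.5% in TS_delta35S_nrpd1. Chloroplast reads made up 1.56% of TS_delta35S_nrpd1 and 0.661 to 0.761% of the other 5 libraries, and tRNA reads 2.21% against 1.15 to 1.49%.

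The comparison of TS_delta35S_nrpd1 with TS_delta35S asked which small RNAs need Pol IV. 24-nt siRNAs were almost absent without it. They made up 57.5% of nuclear reads outside structural RNA in TS_delta35S (57.4 to 57.5) and 3.78% in TS_delta35S_nrpd1 (3.77 to 3.79), and 55.0 to 63.6% in the other 4 libraries. Among all reads of 18 to 28 nt, structural RNA included, 24-nt reads made up 34.2% in TS_delta35S, 7.10% in TS_delta35S_nrpd1, 42.5% in T_WT, 35.1% in S_WT, 37.0% in S_delta35S and 50.4% in TS_WT. In RPM the 24-nt class was 15.2-fold lower in the mutant and the 23-nt class 7.33-fold lower, or 81.2-fold and 39.1-fold per listed miRNA read. The 21-nt class, which holds most miRNAs, made up 75.6% of nuclear reads outside structural RNA in the mutant and 17.6% in TS_delta35S, and 40.8% and 13.8% among all reads of 18 to 28 nt. Its 4.29-fold higher level in RPM turned to 0.804 when levels were scaled to the listed miRNAs, and the 22-nt class went from 1.11 to a 4.797-fold lower level. The listed miRNAs took up 70.9% of the scaling reads in TS_delta35S_nrpd1 and 11.8 to 18.7% in the other 5 libraries, so a fold of this pair in RPM is 5.34 times the same fold per listed miRNA read. Values per listed miRNA read are given for the main classes and for some loci.

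**Figure D1:**
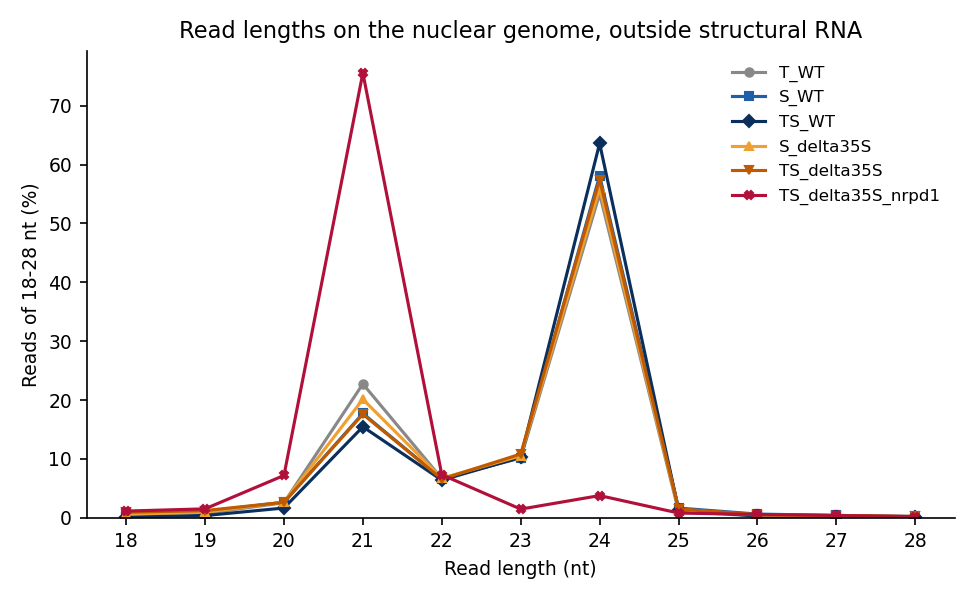
Share of reads of each length (horizontal axis, nt) among reads of 18 to 28 nt on the nuclear genome outside structural RNA (vertical axis, percent), with 1 line per library. The 5 libraries with functional Pol IV peak at 24 nt with 55.0 to 63.6% of reads, and TS_delta35S_nrpd1 peaks at 21 nt with 75.6%.

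The loss of 24-nt siRNAs extended over the whole genome. Of 14767 bins of 500 bp with at least 5 RPM of 24-nt reads in TS_delta35S, 14396 (97.5%) were at least 4-fold lower in TS_delta35S_nrpd1, and 2006 held no 24-nt read there. Pericentromeric bins, within 3 Mb of a centromere, were lower in 7823 of 8104 cases with a median fall of 66.8-fold, and bins on the chromosome arms in 6573 of 6663 cases with a median fall of 89.6-fold. The summed 24-nt level of these bins gave the other order, 29.7-fold lower in pericentromeric bins and 13.7-fold lower on the arms. The median over all bins was 76.3-fold lower. Only 99 of these bins reached the TS_delta35S level in the mutant. In each of the other 4 libraries, 15 to 23 of the same bins were 4-fold lower than in TS_delta35S and 9 or 10 were 4-fold higher. The RdDM siRNA siR1003, which derives from the 5S rRNA gene repeats, stood at 118 RPM in TS_delta35S and had 5 reads in TS_delta35S_nrpd1, 246-fold lower (105 to 757). In the other 4 libraries siR1003 stood between 110.5 and 158 RPM.

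**Figure D2:**
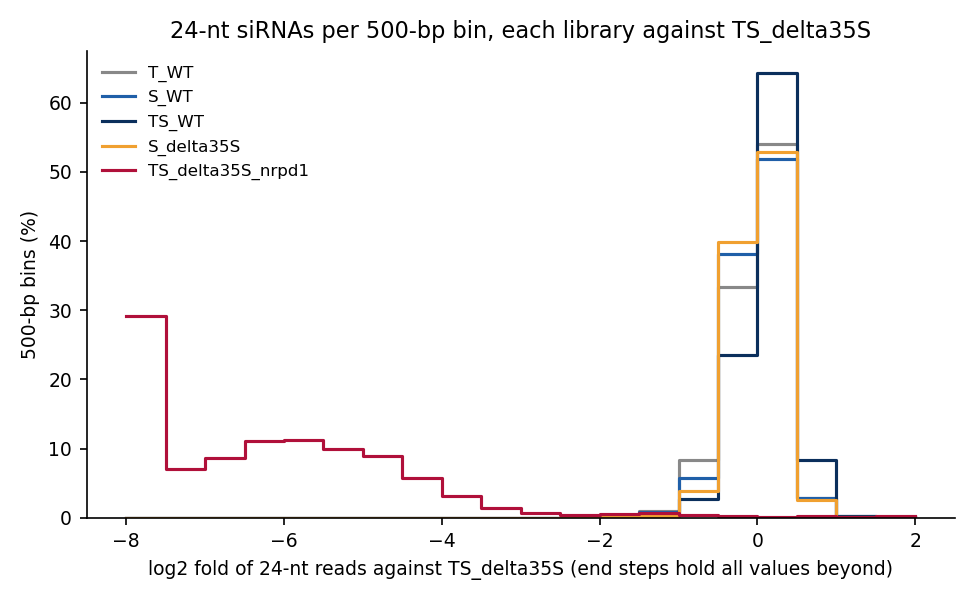
Distribution of the log2 fold of 24-nt reads per 500-bp bin against TS_delta35S (horizontal axis, with all values beyond the ends in the end steps) as a percent of the 14767 bins (vertical axis), with 1 line per library. The median bin of TS_delta35S_nrpd1 lies 76.3-fold lower, and those of the other 4 libraries lie at 1.02 to 1.13 times the TS_delta35S level.

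Loci with known dependence on RdDM showed the same loss. FWA (AT4G25530), whose tandem repeats are silenced by RdDM, went from 7.03 to 0.10 RPM of 24-nt reads between TS_delta35S and TS_delta35S_nrpd1, and SDC (AT2G17690), another tandem-repeat target, from 9.76 to 1.06 RPM. ROS1 (AT2G36490), a DNA demethylase gene with RdDM-dependent promoter methylation, went from 10.6 to 0.58 RPM. Both tandem-repeat loci were at least 2-fold lower in 20-to-24-nt reads, by 103.2-fold for FWA (18.2 to 4106, on 1 read in the mutant) and 4.55-fold for SDC (3.04 to 7.06). Of the list of RdDM-regulated loci, ROS1 was 8.17-fold lower (5.46 to 12.7), and MEA had too few reads to be tested.

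The trans-acting siRNA (TAS) precursors, which give Pol II-dependent siRNAs, did not share this loss. All 5 tested TAS loci had more than 2-fold higher RPM in TS_delta35S_nrpd1, with a median log2 fold of 1.84, but all 5 were below 1 per listed miRNA read. TAS1C (AT2G39675) stood at 3982 RPM in TS_delta35S and 15374 RPM in the mutant, a fold of 3.86 (3.82 to 3.90) that became 0.723 per listed miRNA read. TAS2 (AT2G39681) gave 3.48 and 0.652, and TAS3 (AT3G17185) gave 3.59 and 0.671. TAS4 had too few reads to be tested. The TAS median stood above 91.8% of random lists of loci with like levels, whose middle value was -6.04. The random lists were not matched for read length, and 41.9% of the reads of all tested loci were 24 nt long in TS_delta35S. The percentile can therefore reflect the loss of 24-nt reads at the other loci. Of the silencing machinery, 4 of 12 genes were tested and 3 had at least 2-fold higher RPM. The list had a median log2 fold of 1.75 that stood above 99.9% of random lists, with the same limit. AGO1, the miRNA effector and a miR168 target, was 7.12-fold higher (6.28 to 8.10). It stayed above 1 per listed miRNA read, whereas DCL1 turned from 4.42 to 0.828 and AGO2, a miR403 target, from 2.65 to 0.496.

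The deletion of the 35S promoter asked how far siRNAs of the silencer depend on that promoter, with the target in the TS pair (TS_delta35S against TS_WT) and without it in the S pair (S_delta35S against S_WT). Silencer-linked siRNAs were lower without the promoter in both pairs, and the 21-nt class had the largest fall. These 1487 sequences had no match in the genome at up to 1 mismatch and were chosen from S_WT and S_delta35S against T_WT, without use of the 3 TS libraries. Their summed level was 6779 RPM in TS_WT and 1509 RPM in TS_delta35S, 4.49-fold lower (4.43 to 4.56). It was 7006 RPM in S_WT and 786 RPM in S_delta35S, 8.92-fold lower (8.76 to 9.08). Other choices of sequences and other scalings gave folds of 0.118 to 0.402 in the TS pair, against 0.223, and of 0.0553 to 0.210 in the S pair, against 0.112. T_WT held 9.97 RPM of them as background.

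By length, 21-nt reads were 36.4-fold lower in the TS pair (34.5 to 38.4) and 58.5-fold lower in the S pair (55.2 to 62.0). The 22-nt reads were 4.59-fold lower (4.42 to 4.77) and 8.08-fold lower (7.72 to 8.47). The 24-nt reads were 1.79-fold lower (1.75 to 1.82) and 3.42-fold lower (3.34 to 3.51). The makeup changed accordingly, with 21-nt reads at 55.2% of silencer-linked reads in TS_WT and 6.81% in TS_delta35S, and 24-nt reads at 28.1% and 70.6%. In the S pair, 21-nt reads went from 58.6% to 8.93% and 24-nt reads from 24.8% to 64.6%. Between the lines with the intact silencer, with and without the target, TS_WT stood at 0.968 times S_WT (0.960 to 0.975). That ratio turned to 1.09 per listed miRNA read and 1.40 per read of 18 to 28 nt, so its direction depends on the scaling.

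**Figure D3:**
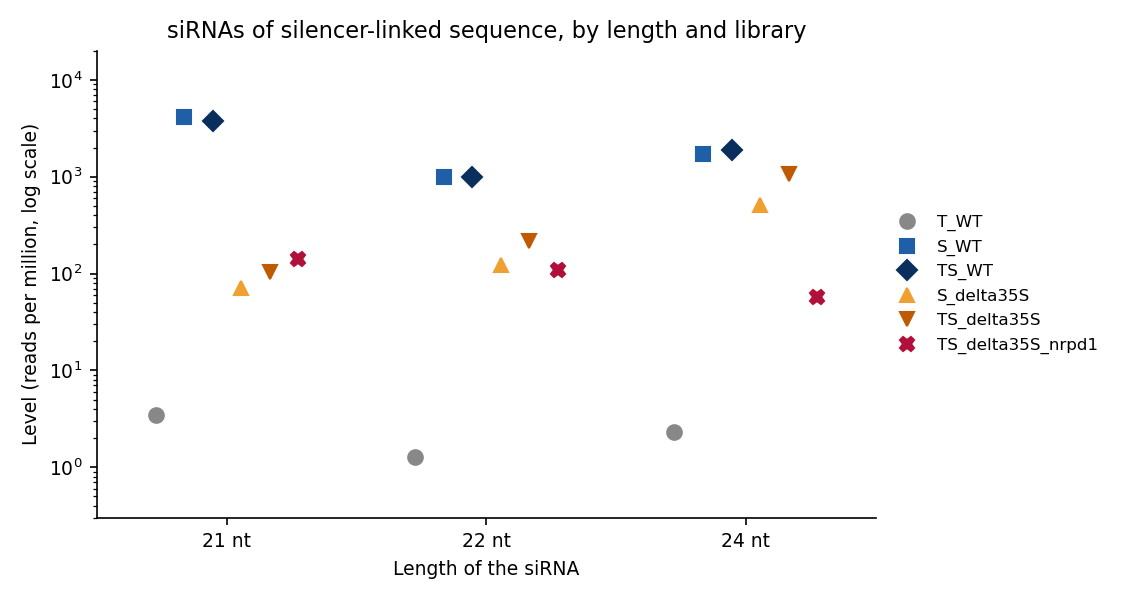
Level of silencer-linked siRNAs (vertical axis, RPM, log scale) of 21, 22 and 24 nt (horizontal axis), with 1 point per library. The 21-nt level is 3740.1 RPM in TS_WT and 4105 RPM in S_WT against 102.7 RPM in TS_delta35S and 70.2 RPM in S_delta35S, and the 24-nt level is 1065 RPM in TS_delta35S against 57.5 RPM in TS_delta35S_nrpd1.

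The siRNAs that remained without the promoter depended on Pol IV at 24 nt. In TS_delta35S_nrpd1, silencer-linked reads were 4.37-fold lower than in TS_delta35S (4.22 to 4.53) and their 24-nt class 18.5-fold lower (17.1 to 20.1), or 98.98-fold per listed miRNA read. The 22-nt class was 1.98-fold lower (1.85 to 2.12), or 10.6-fold per listed miRNA read. The 21-nt class stood at 141 RPM against 102.7 RPM in TS_delta35S, a fold of 1.37 (1.28 to 1.48) that turned to 0.257 per listed miRNA read. The whole set was 23.3-fold lower per listed miRNA read.

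Overlapping silencer-linked sequences were joined into 12 contigs of 50 to 99 nt, 808 nt in all, and these fell into separate classes. The 8 contigs that were at least 4-fold lower in the TS pair were 27.97-fold lower as a class in the S pair too (26.8 to 29.2), with 3925 RPM in S_WT and 140.3 RPM in S_delta35S. Their 21-nt reads were 184-fold lower in the S pair (161.18 to 211) and their 24-nt reads 9.80-fold lower (9.27 to 10.4). In the TS pair, which served to define this class, the level was 19.1-fold lower (18.4 to 19.8). Without Pol IV, 24-nt reads of these contigs were a further 9.46-fold lower (7.98 to 11.3), or 50.5-fold per listed miRNA read. Their 21-nt and 22-nt reads were 3.04-fold (2.57 to 3.604) and 1.996-fold (1.69 to 2.36) higher in RPM, which turned to 0.569 and 0.374 per listed miRNA read.

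Contig 1, of 69 nt, held the most reads. It matched itself at a shift of 42 nt with 92.6% identity over 27 nt, as a tandem repeat does. Reads of contig 1 were 28.6-fold lower in the TS pair (26.9 to 30.5) and 39.0-fold lower in the S pair (36.6 to 41.7). Contig 2, of 99 nt, was 10.98-fold lower (10.2 to 11.8) and 13.6-fold lower (12.6 to 14.7). Contig 3, of 51 nt, was 40.3-fold lower (34.4 to 47.7) and 56.4-fold lower (47.4 to 67.7). Contigs 4 and 5, of 61 and 96 nt, matched the bla gene of common cloning vectors. They were 7.54-fold lower (6.81 to 8.37) and 13.7-fold lower (11.6 to 16.2) in the TS pair, and 19.8-fold (17.2 to 22.9) and 22.6-fold (18.7 to 27.6) in the S pair.

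The other 4 contigs, numbered 8, 9, 10 and 12 and named after their values were seen, did not share the fall. Their reads were 69.9 to 75.1% 24-nt in the 4 libraries with the silencer and functional Pol IV. As a class they stood at 395 RPM in TS_delta35S against 208 RPM in TS_WT, 1.90-fold higher (1.83 to 1.98). In the S pair the fold was 0.745 (0.708 to 0.785), with 162 RPM in S_delta35S and 217 RPM in S_WT. They were 44.8-fold lower in TS_delta35S_nrpd1 than in TS_delta35S (36.4 to 55.6), and 120.0-fold lower at 24 nt (80.5 to 188), or 239-fold and 641-fold per listed miRNA read. A wider choice of sequences, made after these results were seen, gave 18 contigs with 3668 nt in all. In that choice 14 contigs without the fall had TS-pair folds of 1.27 to 2.33 and S-pair folds of 0.393 to 0.962.

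**Figure D4:**
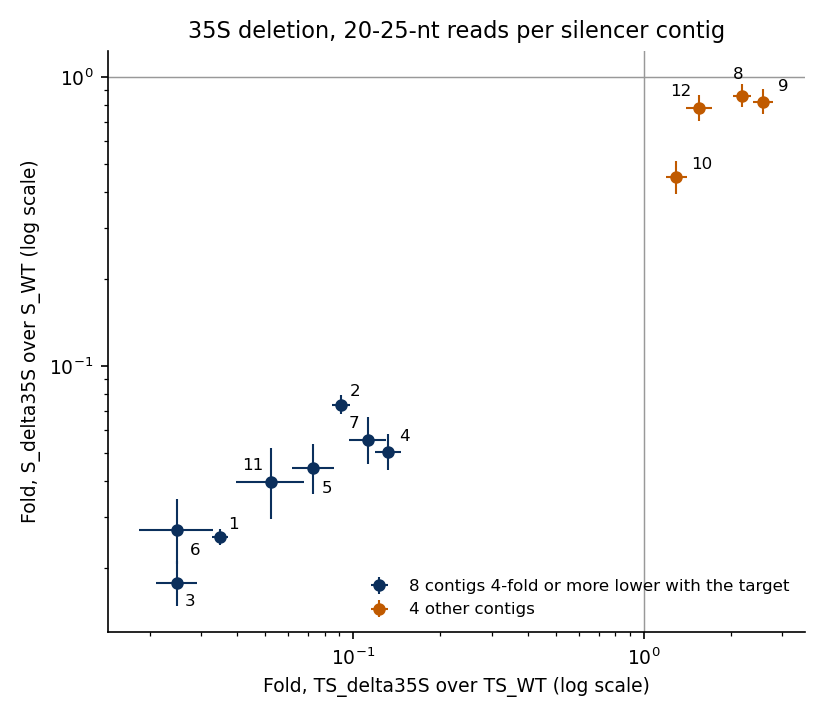
Fold of 20-to-25-nt reads per silencer contig on log scales, TS_delta35S over TS_WT on the horizontal axis and S_delta35S over S_WT on the vertical axis, with 1 numbered point per contig and exact 95% intervals as bars. The 8 contigs used as 1 class lie at the lower left, with TS-pair falls of 7.54-fold to 40.3-fold, and the 4 others lie at 1.30 to 2.58 on the horizontal and 0.450 to 0.862 on the vertical axis.

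Sequences chosen for their level in T_WT against the lines with the silencer alone are called target-linked. Their origin in the target locus was not shown. The choice leaves out sequences that the silencer lines also produce, such as those of the shared enhancer, and so limits the set. Target-linked siRNAs were few, with 5 sequences and 236 reads in T_WT, 81.8% of them 24 nt long, and no contig could be joined from them. TS_WT had 411 such reads, 1.58-fold more than T_WT in RPM (1.35 to 1.87). TS_delta35S had 3 reads, 57.0-fold lower than T_WT (19.3 to 278), and TS_delta35S_nrpd1 had 9 reads, 14.4-fold lower (7.46 to 31.9). With a minimum of 5 in place of 10 reads in T_WT, the fold of TS_WT over T_WT reversed to 0.728, and those of TS_delta35S and TS_delta35S_nrpd1 moved to 0.172 and 0.204. Per listed miRNA read, the fold of TS_WT was 2.504 and that of TS_delta35S_nrpd1 0.0183.

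Probes of common vector parts, written from general knowledge, asked which introduced elements give siRNAs. Exact matches to the 35S promoter numbered 25 in S_WT and 24 in TS_WT, 0 in both delta35S libraries, 4 in TS_delta35S_nrpd1 and 1 in T_WT. The EGFP coding region gave 57 reads in T_WT (3.01 RPM) and 99 in TS_delta35S_nrpd1 (9.50 RPM), but 0 in TS_WT and 4 in TS_delta35S. EGFP was thus 32.6-fold higher in TS_delta35S_nrpd1 than in TS_delta35S (12.3 to 122), and 6.10-fold per listed miRNA read. The target-linked sequences had another order, with 411 reads in TS_WT and 9 in TS_delta35S_nrpd1. The bla coding region, a probe added after the contigs were seen, gave 844 RPM in TS_WT and 75.7 RPM in TS_delta35S, 11.2-fold lower (10.5 to 11.9). It gave 865 RPM in S_WT and 37.4 RPM in S_delta35S, 23.2-fold lower (21.4 to 25.1).

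The start of the HPT hygromycin-resistance gene went the other way. HPT reads were 3.34-fold higher in the TS pair (2.83 to 3.96), from 9.93 to 33.2 RPM, and 1.59-fold higher in the S pair (1.37 to 1.85), from 19.2 to 30.6 RPM. HPT stood at 131 RPM in TS_delta35S_nrpd1, 3.94-fold higher than in TS_delta35S, which turned to 0.737 per listed miRNA read. T_WT had 0 HPT reads. The nos terminator was 3.21-fold higher in the TS pair (1.98 to 5.33) and 0.996 in the S pair (0.680 to 1.46). The NPTII start gave 27 reads in TS_delta35S_nrpd1 and 12 in T_WT, and 3 each in TS_WT and TS_delta35S.

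Mature miRNAs asked whether the endogenous small RNA programme differed between the lines. In the TS pair, 4 of 7 tested nutrient-responsive miRNAs were at least 2-fold lower. The other 3, miR399, miR2111 and miR395, had RPM folds of 1.45, 1.18 and 1.05, which turned below 1 per read of 18 to 28 nt. Of 44 miRNAs tested, 6 were at least 2-fold higher and 4 lower in RPM, against 0 and 7 per read of 18 to 28 nt, 4 and 4 per listed miRNA read, and 0 and 5 with median-ratio size factors. The median log2 fold was 0.28, and relative to that median 2 were higher and 4 lower. All 4 lower ones belonged to the nutrient list, which had a relative median of -1.31. They were miR397 and miR408, copper-responsive regulators of laccases and plantacyanin, at 0.170 (0.129 to 0.221) and 0.488 (0.453 to 0.525), miR398, a regulator of copper superoxide dismutases, at 0.290 (0.280 to 0.299), and miR827 of phosphate uptake at 0.312 (0.289 to 0.338). These 4 stayed below 1 under each scaling. The rRNA share of this pair was 35.8% in TS_delta35S against 14.2% in TS_WT. Relative to the median, 1 of 13 development miRNAs (miR394) and 1 of 15 others (miR169) were 2-fold higher. None of the phase-change, silencing-feedback, ta-siRNA-trigger or pollen miRNAs, 9 tested in all, changed by 2-fold relative to the median.

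In the S pair few miRNAs differed. Of 44 tested, 2 were higher and 1 lower in RPM, against 3 and 0 per read of 18 to 28 nt, 2 and 2 per listed miRNA read, and 2 and 1 with median-ratio factors. The median log2 fold was -0.09. The higher ones were miR397 at 3.41 (1.95 to 6.33) and miR395, a regulator of sulfate assimilation, at 2.60 (0.899 to 9.15), whose interval includes 1. The lower one was miR402 at 0.451 (0.212 to 0.915). Relative to the median, 3 of 7 nutrient miRNAs were higher, miR398 being the other, with 1.90 before that step (1.80 to 2.0002). The rRNA shares were 29.5% in S_delta35S and 34.5% in S_WT. Among the development, phase-change, silencing-feedback, trigger and pollen lists no member passed 2-fold in this pair.

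In the Pol IV mutant nearly every miRNA had a higher RPM than in TS_delta35S, and the 5 that lay at least 2-fold above the median were all on the nutrient list. Of 44 tested, 43 were higher and 0 lower in RPM, 42 and 0 per read of 18 to 28 nt, 5 and 8 per listed miRNA read, and 5 and 1 with median-ratio factors. The median log2 fold was 1.86. Relative to it, 5 of 7 nutrient miRNAs were at least 2-fold higher, with a list median of 1.74, and miR399 and miR2111 stood at 0.850 and 1.14. The 5 were miR397, 20.5-fold (15.9 to 26.9), miR398, 20.4-fold (19.8 to 21.01), miR408, 16.6-fold (15.5 to 17.7), miR827, 12.1-fold (11.3 to 13.1), and miR395, 10.98-fold (5.49 to 24.9). Per listed miRNA read these were 3.84, 3.82, 3.11, 2.27 and 2.06. Of these, miR397, miR398, miR408 and miR827 were also at least 2-fold lower in TS_delta35S than in TS_WT, so their folds here rest on a reference below TS_WT. Together, miR397, miR398 and miR408 made up 1.11% of listed miRNA reads in the mutant and 1.09% in TS_WT, and less in each other library. On that scale their summed level in the mutant was thus close to that of TS_WT, which has functional Pol IV. miR169 was the 1 miRNA below the median by 2-fold. The pollen miRNAs miR845a and miR845b stood at 2.66 (2.39 to 2.97) and 3.72 (3.32 to 4.18), or 0.735 and 1.03 relative to the median. No member of the phase-change, development, silencing-feedback or trigger lists passed 2-fold relative to the median. The rRNA shares were 38.5% and 35.8%, and the chloroplast shares 1.56% and 0.674%.

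The comparisons of TS_WT with S_WT and with T_WT asked what the silencer and target together add. Copper-responsive miRNAs were higher in TS_WT than in S_WT, with miR397 at 24.6-fold (14.99 to 43.3), miR398 at 7.92-fold (7.57 to 8.28) and miR408 at 4.63-fold (4.19 to 5.13). Of 43 tested, 3 were higher and 4 lower in RPM, against 4 and 0 per read of 18 to 28 nt, 3 and 3 per listed miRNA read, and 3 and 1 with median-ratio factors. The median log2 fold was -0.36, and relative to it 3 of 6 nutrient miRNAs were higher, with a list median of 1.73. The 3 lower ones relative to the median were miR170 and miR394 of the 13 development miRNAs, and miR402. The rRNA shares were 14.2% in TS_WT and 34.5% in S_WT.

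TS_WT and T_WT, the libraries with the lowest rRNA shares (14.2% and 17.3%), differed less. Of 43 tested, 0 were higher and 4 lower in RPM, against 0 and 4 per read of 18 to 28 nt, 2 and 0 per listed miRNA read, and 2 and 0 with median-ratio factors. The 4 were miR156, a regulator of phase change, at 0.391 (0.369 to 0.415), miR390, a ta-siRNA trigger, at 0.479 (0.467 to 0.492), and the development miRNAs miR170 and miR394. The median log2 fold was -0.46, and relative to it none of these was 2-fold lower. Relative to that median, miR397 and miR398, 2 of 7 nutrient miRNAs, were higher by 2.56 and 2.31, from folds of 1.86 (1.61 to 2.16) and 1.67 (1.64 to 1.71). In both comparisons no silencing-feedback or pollen miRNA passed 2-fold on either scale.

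**Figure D5:**
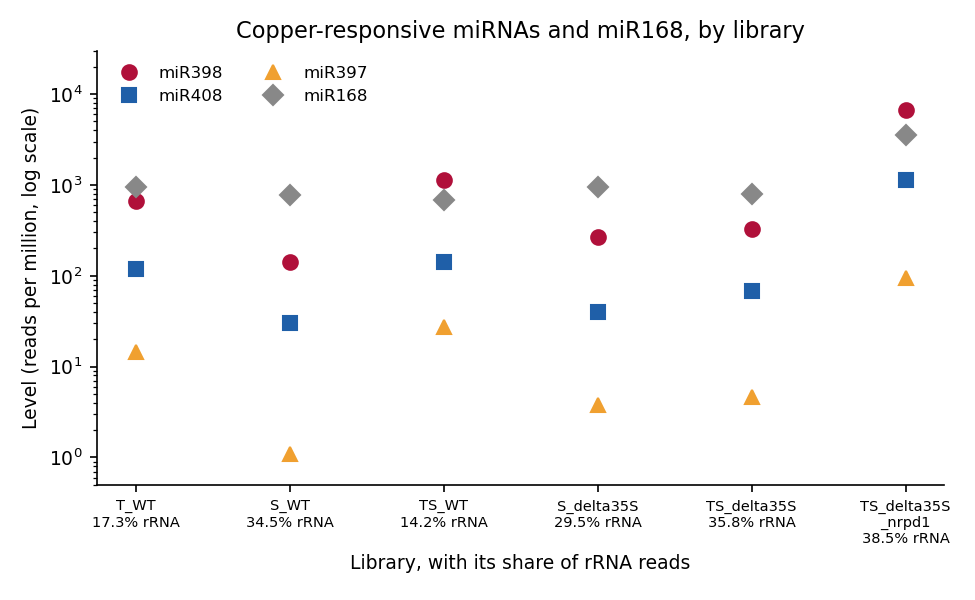
Level of 3 copper-responsive miRNAs and of miR168 for reference (vertical axis, RPM, log scale) in each library (horizontal axis, with its share of rRNA reads), with 1 point per miRNA and library. Summed over the 3, the level is 173 RPM in S_WT, 312 in S_delta35S, 398 in TS_delta35S, 804 in T_WT, 1287.5 in TS_WT and 7842 in TS_delta35S_nrpd1.

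Annotated loci asked where in the genome small RNAs changed. For the 35S deletion, 64 of 6631 loci differed by 4-fold or more in the TS pair, 49 higher and 15 lower, and 33 of 7219 in the S pair, 18 higher and 15 lower. Per listed miRNA read the TS pair gave 25 higher and 16 lower, and with a minimum of 30 reads 414 higher and 22 lower among 11495. Of the 49, 46 were protein-coding genes, and 28.4% of their reads were 24 nt long in TS_delta35S, against 42.5% over all tested loci. This pair is the one with rRNA shares of 35.8% and 14.2%. The list loci gave no 2-fold change in either pair. The 5 tested TAS loci had median log2 folds of 0.04 and -0.11, above 62.8% and 22.2% of random lists. The silencing machinery, with 3 and 4 genes tested, had 0.14 and -0.01, above 89.3% and 37.6%. FWA, SDC and ROS1 were the other loci tested.

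Across both pairs, 3 of 6381 loci differed by 4-fold or more in the same direction, 1 higher and 2 lower, where independent lists would share 0.0845 and 0.0155. The lists need not be independent, since S_delta35S is a segregant of TS_delta35S. A state inherited by both delta35S lines cannot be told apart from an effect of the deletion. The lncRNA locus AT5G04435 (chromosome 5, 9818925 to 9819175) was 156-fold lower in the TS pair (71.4 to 425) and 71.1-fold lower in the S pair (41.3 to 134). The protein-coding gene AT4G13030 (chromosome 4, 7607241 to 7609876) was 15.2-fold lower (7.19 to 38.3) and 16.5-fold lower (9.22 to 32.6). The lncRNA locus AT5G04815 (chromosome 5, 10794902 to 10795442) was 18.5-fold higher (9.42 to 41.6) and 7.57-fold higher (4.05 to 15.7). Below 4-fold in at least 1 pair, AT3G44006 was lower by 207-fold (57.1 to 1715, on 2 reads) and 2.88-fold (2.39 to 3.50), and AT1G06833 by 3.49-fold (2.41 to 5.19) and 2.64-fold (2.10 to 3.32).

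In the TS pair, the largest rises were at AT5G04815 and at MPC (AT3G19350), an imprinted gene for a poly(A)-binding protein C-terminal domain, which was 14.05-fold higher (11.6 to 17.1). LCR26 (AT4G29290), a cysteine-rich secreted protein gene, was 11.2-fold higher (6.70 to 19.8). VTC2 (AT4G26850), an ascorbate biosynthesis gene, was 7.86-fold higher (4.95 to 13.0), and the pseudogene AT2G05690 was 7.63-fold higher (5.41 to 10.99). The largest falls were at AT3G57480, 973-fold lower on 1 read (174 to 38443), AT5G04435, AT3G08935, at least 151-fold lower with 0 reads, AT3G44006, and scpl5 (AT1G73290), 45.2-fold lower (19.2 to 140). Of the scpl5 reads, 22.6% had 1 place in the genome. The scpl5 locus was also among the largest rises of TS_WT against T_WT, and MPC and LCR26 among the largest falls. At these loci TS_WT thus differed from T_WT as well.

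In the S pair, the largest rises were at AT4G22900, 273-fold higher against 1 read in S_WT (48.7 to 10822), AT5G51930, 99.7-fold (38.7 to 368), the overlapping lncRNA loci AT1G07457 and AT1G07463, 53.1-fold (20.5 to 196) and 50.5-fold (19.5 to 187), and the F-box pseudogene AT2G32291, 45.4-fold (30.1 to 71.8). Besides AT5G04435, the largest falls were at AT4G32370, 44.9-fold lower (25.4 to 87.5), AT3G28899, 32.7-fold (22.4 to 49.5), AT5G21125, 28.6-fold (17.9 to 48.8), and AT2G01422, 19.98-fold (15.3 to 26.6). AT4G22900 was also among the largest rises of TS_WT against S_WT, and AT4G32370 and AT5G21125 among its largest falls. At these loci S_WT thus differed from TS_WT too, which has the promoter. The other loci named for the S pair were not among those extremes.

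In TS_delta35S_nrpd1 against TS_delta35S, annotated loci with at least 100 reads mostly lost their small RNAs. Of 5815 such loci, 4014 were lower by 4-fold or more and 255 higher, or 4361 and 4 per listed miRNA read. With a minimum of 30 reads, 5775 of 12783 (45.2%) were lower and 550 higher, and the median log2 fold was 0.01. Pseudogenes were lower in 2297 of 2315 cases, transcribed pseudogenes in 172 of 187 and lncRNA loci in 178 of 247. Transposable elements had no class of their own in the annotation, and how many of the pseudogenes are transposon genes was not determined. Protein-coding genes were lower in 1241 and higher in 134 of 2721 cases, and miRNA genes lower in 33 and higher in 84 of 205. The largest falls were at the pseudogene AT5G28535, 2863-fold lower on 1 read (513 to 113096), AT2G04062, 2339-fold (647 to 19321, on 1.5 reads rounded to 2), AT5G28560, 941-fold (403 to 2898), and the lncRNA loci AT1G06417, 911-fold (509 to 1825), and AT3G05025, 682-fold (432 to 1152). The largest rises were at MIR397b (AT4G13555), 33.3-fold (25.3 to 44.6), MIR397a (AT4G05105), 20.8-fold (16.2 to 27.2), MIR398b (AT5G14545), 20.3-fold (19.4 to 21.1), MIR398c (AT5G14565), 20.2-fold (19.4 to 21.1), and AT5G14550, which overlaps MIR398b. Per listed miRNA read these were 6.23-fold, 3.90-fold, 3.79-fold, 3.79-fold and 3.78-fold. MIR398b and MIR398c share their mature sequence, and 0.139% and 0.064% of their reads had 1 place.

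Between TS_WT and S_WT, 22 of 6896 loci were higher and 243 lower by 4-fold or more, or 24 and 112 per listed miRNA read. With a minimum of 30 reads, 31 were higher and 1148 lower among 12353. Of the 243, 236 were protein-coding, and 28.6% of their reads in S_WT were 24 nt long against 42.6% over all tested loci, in the pair with rRNA shares of 14.2% and 34.5%. The largest rises were at AT4G22900, 172-fold higher against 1 read (30.6 to 6823), the pseudogene AT4G13470, 47.8-fold (31.1 to 77.4), MIR397b, 25.03-fold (16.6 to 39.7), MIR397a, 22.7-fold (14.2 to 38.5), and HS1 (AT3G17210), a heat-stable antimicrobial protein gene, 18.8-fold (11.3 to 33.97). The largest falls were at AT3G26775, at least 467-fold lower with 0 reads, AT5G21125, 639-fold on 1 read (114 to 25301), AT3G09960, 425-fold (117 to 3515), AT5G43755, 391-fold (108 to 3237), and AT4G32370, 95.4-fold (45.9 to 239). AT3G09960 and AT5G43755 had 2.5 and 1.5 reads in TS_WT, both rounded to 2. AGO4, the RdDM effector, was the 1 of 4 tested silencing genes that was 2-fold lower, at 0.403 (0.263 to 0.609). AGO4 stood at 1.69 RPM in T_WT and 1.82 RPM in TS_WT, the libraries with the least rRNA, and at 3.86 to 4.89 RPM in the others. Its difference cannot be told apart from RNA quality. The list median of -0.39 stood above 3.92% of random lists. TAS loci had a median of -0.17, above 5.47% of random lists, with 0 of 5 beyond 2-fold.

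TS_WT and T_WT differed at 9 loci that were higher and 10 that were lower among 6665, or 15 and 7 per listed miRNA read. The largest rises were at scpl5, 19.5-fold (11.8 to 34.5), AT5G11370, 11.3-fold (8.10 to 16.1), AT5G35737, 10.7-fold (8.93 to 12.9), AT3G03620, 5.11-fold (3.57 to 7.496), and MIR397b, 4.51-fold (3.81 to 5.36). The largest falls were at AT5G42410, 86.8-fold on 3 reads (29.4 to 424), AT1G32140, 70.9-fold (35.7 to 165), AT3G25930, 26.4-fold (11.8 to 73.1), LCR26, 11.6-fold (7.07 to 20.4), and MPC, 9.67-fold (8.01 to 11.8). MPC and LCR26 were thus lower in TS_WT than in both T_WT and TS_delta35S. TAS loci and the silencing machinery, with 5 and 3 tested, had no 2-fold change. Their medians were -0.19, above 11.3% of random lists, and -0.39, above 0.83% of random lists. The random lists were not matched for read length. In this pair a fold in RPM is 0.633 times the same fold per listed miRNA read. FWA, SDC and ROS1 did not reach 2-fold in this pair or in TS_WT against S_WT.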

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

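All tests of explanations in this part were chosen after the results were seen, and none of the differences between the TS pair and the S pair was itself tested, since there are no replicates.

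Silencer contigs without the fall went opposite ways in the pairs, 1.90-fold higher in TS_delta35S than in TS_WT and at 0.745 in S_delta35S against S_WT, a ratio of folds of 2.55 that was 1.54 per read of 18 to 28 nt. Scaling is argued against as the whole cause of the opposite directions, since the TS-pair fold stayed above 1 under 4 scalings, with a lowest value of 1.30 (1.245 to 1.35), while the S-pair fold stayed between 0.619 and 0.839. These were the RPM, per listed miRNA read, per read of 18 to 28 nt and per 24-nt nuclear read outside structural RNA. The TS pair defined the class by the lack of a 4-fold fall, so its fold there is not a free readout. A general rise of 24-nt siRNAs in TS_delta35S is argued against too, because the median fold of 16329 24-nt bins in that pair was 0.858. The presence of the target locus, which differs between the pairs, stays open as untested, as do differences between single plants or preparations.

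Copper-responsive miRNAs also went opposite ways, with a ratio of the TS-pair to the S-pair fold of 0.0498 for miR397, 0.153 for miR398 and 0.370 for miR408, from folds of 0.170, 0.290 and 0.488 in the TS pair and 3.41, 1.90 and 1.32 in the S pair. Scaling is argued against for the TS pair, where the highest fold of the 3 together over 4 scalings was 0.309. For TS_delta35S_nrpd1 (38.5% rRNA), the rRNA share as the only cause is argued against, since it was 3.69-fold higher per listed miRNA read (3.59 to 3.80) than TS_delta35S (35.8%). The 3 made up 1.11% of listed miRNA reads in TS_delta35S_nrpd1, close to the 1.09% in TS_WT. For the other libraries, RNA quality cannot be told apart from the lines. T_WT and TS_WT had the least rRNA (17.3% and 14.2%) and at least 2.02 times the RPM of the other 3, or 1.44 times per listed miRNA read. TS_delta35S, with more rRNA than S_WT (34.5%) and S_delta35S (29.5%), stood above both. Over 4 scalings it was 2.26 to 2.41 times S_WT and 1.11 to 1.53 times S_delta35S, with no known spread between plants. Other differences in RNA quality or growth stay open, as TS_delta35S_nrpd1 also exceeded TS_delta35S in chloroplast reads (1.56% against 0.674%), tRNA (2.21% against 1.34%) and snRNA and snoRNA (0.781% against 0.428%), and no biological explanation was tested.

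Other miRNAs whose folds lay on opposite sides of 1 in the TS and S pairs, with both intervals excluding 1 and folds at least 2-fold apart, were miR402, with a ratio of 5.18 (2.33, 1.11 to 5.11, against 0.451, 0.212 to 0.915), and miR170, with 3.604 (2.21, 1.41 to 3.50, against 0.614, 0.411 to 0.909). miR394 gave a ratio of 3.27 (2.45, 2.30 to 2.61, against 0.749, 0.710 to 0.792) and miR171 one of 2.63 (1.90, 1.76 to 2.05, against 0.722, 0.673 to 0.774). miR167 gave 2.07 (1.48, 1.43 to 1.53, against 0.715, 0.690 to 0.741). Per read of 18 to 28 nt, the ratios were 3.13 for miR402 and 2.18 for miR170, but fell below 2 for miR394 (1.97), miR171 (1.59) and miR167 (1.251), whose TS-pair fold was then 1.007. With median-ratio factors they were below 2 for miR171 (1.97) and miR167 (1.55). The miR402 values rest on 20 and 13 reads in TS_delta35S and TS_WT, and 13 and 25 in S_delta35S and S_WT. Each of these miRNAs had its lowest RPM in TS_WT, such as miR394 with 73.4 RPM against 153 RPM in T_WT. The rRNA shares were 35.8% in TS_delta35S, 14.2% in TS_WT and 17.3% in T_WT, and a part of RNA quality in these differences was not tested.

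Another signal that no comparison of the report used lay in 28 sequences chosen for at least 10 reads in TS_WT and near absence in T_WT, S_WT and S_delta35S. They had 1631 reads in TS_WT, 88.6% of them 24 nt long, and 0, 0 and 3 reads in the other 3 libraries, values that the choice itself sets. In the libraries not used for the choice they had 272 reads in TS_delta35S and 2 in TS_delta35S_nrpd1, 103.2-fold lower (28.3 to 857).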

How the results depend on the processing

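Each group has 1 library, so no replicate number pairs libraries, and a fit of the deletion over both pairs with the target as a block, which would leave 1 residual degree of freedom, was not run. The choices added after seeing the data are named in the description of the processing. Unless a cause is given, the cause was not tested. Values are folds unless said otherwise.

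Scaled to listed miRNAs, the silencer-linked fold was 0.198 in the TS pair, 0.0932 in the S pair and 0.0429 in nrpd1, the target-linked fold against T_WT 2.504 in TS_WT and 0.0183 in nrpd1, and 41 loci in the TS pair and 136 in TS_WT against S_WT changed. Per read of 18 to 28 nt, the silencer-linked fold was 0.152, 0.126 and 0.208, and 4 miRNAs differed between TS_WT and S_WT. With median-ratio factors, 5 miRNAs changed in the TS pair, 6 in nrpd1, 4 in TS_WT against S_WT and 2 in TS_WT against T_WT. With exact miRNA sequences, 7 changed in TS_WT against T_WT.

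The 24-nt share was 34.8% in TS_delta35S and 7.02% in nrpd1 among reads with an exact match, and 57.5% and 3.78% outside structural RNA. At 20 RPM, 4220 bins were lost, since fewer bins were tested. At 5 reads the silencer-linked fold was 0.283, 0.155 and 0.327, and at 50 reads 0.118, 0.0553 and 0.159. With the filter on exact matches it was 0.402 in the TS pair and 0.210 in the S pair. Chosen from S_WT alone it was 0.206, 0.0960 and 0.176, and from S_delta35S alone 0.379, 0.201 and 0.178. At 5 reads the target-linked fold of TS_WT over T_WT reversed to 0.728, and was 0.172 in TS_delta35S and 0.204 in nrpd1. At 50 reads it was 0 in both. At 30 reads, where more loci were tested, 436 loci changed in the TS pair (414 higher), 56 in the S pair, 1179 in TS_WT against S_WT (1148 lower), 34 in TS_WT against T_WT and 5 in both 35S pairs.

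Under these alternatives the silencer-linked fold stayed below 1 in all 20 values, and total counts of loci in nrpd1 and of miRNAs in the S pair stayed within 1.5 times their value. Within these totals, higher loci in nrpd1 went from 255 to 4 per listed miRNA read. In the wider choice, contigs with the fall went from 8 of 12 to 4 of 18, and the total length from 808 to 3668 nt. That choice also had a minimum of 100 nt in place of 50 nt, so the contig counts are not a like measure. Depth limits target-linked values, which rest on 3 and 9 reads in TS_delta35S and nrpd1, and probe values on as few reads.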

Other observations

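The tests of explanations in this part, and the bins compared here, were chosen after the results were seen.

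Apart from the introduced loci, the 5 libraries with functional Pol IV had nearly the same 24-nt bins. Of 9881 bins at 10 RPM or more in at least 1 of these 5 libraries, 83 (0.840%) were at or below 0.5 RPM in another. S_WT alone held 6 bins that were off in the other 4, S_delta35S alone 5, T_WT alone 2, TS_WT alone 1 and TS_delta35S alone 0. Bins off in 1 library and on in the other 4 numbered 3 in TS_delta35S, 3 in S_WT, 1 in T_WT, 1 in S_delta35S and 0 in TS_WT. In both 35S deletion pairs, 2 bins were on in the delta35S libraries and off in TS_WT and S_WT, at AT1G60987 and AT1G08673. Another 4 were off in the delta35S libraries, at AT4G05520, at AT5G04435 and AT5G27730, at AT5G59810, and on chromosome 5 from 15742001 to 15742500, where no locus is annotated. These loci were named after their values were seen. Both delta35S lines share descent, so an inherited state cannot be told apart from an effect of the deletion at these bins.

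The 21-nt reads of silencer contig 1 were 3.74-fold higher in RPM in TS_delta35S_nrpd1 than in TS_delta35S (2.97 to 4.75), after a 203-fold fall in the TS pair. Reads carried over from other libraries are argued against as the whole source, since these reads reached 0.532% of the S_WT and TS_WT total (0.472 to 0.597), above the 0.125% of siR1003 (0.0406 to 0.292), which needs Pol IV. Scaling may account for the rise, because per listed miRNA read the fold was 0.701 (0.557 to 0.888). No biological explanation was tested.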
